A study of Mus musculus with 34 samples.

How the data were processed

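Hepatocytes were separated on Percoll with exclusion of propidium iodide, and macrophages were sorted as F4/80 and CD45 positive cells, per the labels' protocols. RNA was made into QuantSeq 3′ forward libraries and read as single 50 bp reads on a HiSeq4000, per the labels. Reads were trimmed with Trimmomatic 0.39 and aligned with HISAT2 2.1.0 to GRCm38/mm10, per the submitters' processing notes. The authors deposited raw read counts per gene symbol, 1 column per library, for 24951 genes in hepatocytes and 26233 in macrophages. The counter, the annotation and the strand setting are not given in the sources used here. Totals were 596380 to 7535053 counts, so that 3 counts stood for 0.398 to 5.03 CPM. Gene positions are those of the GRCm38 reference annotation.

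Mice were grouped by the genotype and treatment labels. For 2 libraries another label gave the other genotype, and these were kept in the group of the genotype label, left out, or moved to the knockout group. The file series was read from the widest gap in the numbers of the sequencing files, 14 to 25. Pairs of libraries of a group differed by more than sampling noise (chi-square per degree of freedom 5.16 to 42.5), so no library was taken for a copy of another.

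Counts were analysed in R 4.3.3 with edgeR 4.0.16, 1 fit of 4 groups per cell type, with filterByExpr, TMM factors, robust dispersion and quasi-likelihood F tests, and Benjamini-Hochberg adjustment within each comparison at 0.05. Standard errors are the log2 fold change over the square root of F and are approximate. The comparisons were CCl4 in controls, knockout without and after CCl4, CCl4 in knockout mice, and their interaction. Means of CPM use TMM-normalised values unless a value is given as CPM of the library total. Gene lists, 41 in number, were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01 and with an estimated one where 4 or more genes were measured, and with fry, and each list was also adjusted alone. Camera treats genes as nearly independent at that preset, and its p values are lower than the mice alone would give. For a group with 0 counts the bound was computed over the group from a floor of 3 counts, and for 1 to 3 counts the ratio has an exact 95% counting interval (confidence level 0.95).

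Genes were named by a rule: Yap1 and Wwtr1, the 6 called genes with the largest log2 fold change each way among those of at least 10 CPM in the higher group (4 each way for CCl4 in knockout mice and the interaction, passing over clone names, predicted genes and receptor segments), and up to 4 genes of lowest p from each list described. Of the genes this rule gives, 2 are not reported here. Others are said to have been named after their values were seen. The groups, comparisons, lists, naming rule and first alternatives were set before the data were examined. These alternatives were RLE factors, no filter, DESeq2 1.42.0, limma voom, fits that were not robust, fits of the contrast's own groups, a batch as a term and leaving out each library in turn. That the file series would serve as the batch was decided once the deposited sample tables had been read. A further 11 alternatives, among them the second series alone and thinning every library to the smallest total of its cell type, were chosen after seeing the data.

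The scripts were tested on simulated counts with 200 changed genes. Recovery of 4-fold changes ranged from 20% (macrophage interaction, 10815 genes) to 86% (CCl4 in control hepatocytes, 9679 genes), and of 2-fold changes from 0% to 41%. False calls made up 3.75% to 11.4% of calls, above the nominal 5% in 8 of 10 comparisons. Of 20 unchanged lists 0 were called by camera in each of the 2 comparisons tested so. The simulated genes were drawn independently of each other, so this does not test camera where genes vary together.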

Results

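Gene expression was measured in hepatocytes and liver macrophages of mice in which the transcriptional coactivators YAP and TAZ (genes Yap1 and Wwtr1) could be deleted from biliary epithelial cells. Knockout mice carried floxed alleles of both genes and a tamoxifen-inducible Cre recombinase under the osteopontin promoter, and their Cre-negative siblings served as controls. Tamoxifen was given at 1.6 mg/kg for 5 days at 7 to 8 weeks of age, followed by a washout of 3 weeks. Part of each genotype then received carbon tetrachloride (CCl4), a toxicant that pericentral hepatocytes convert to a reactive radical, at 1 ml/kg, and livers were taken 48 h later. The comparisons ask how the loss of YAP and TAZ in bile duct cells bears on the other cells of the liver, with and without injury. Hepatocytes came from 6 control and 5 knockout mice without CCl4 and from 3 control and 4 knockout mice with it. Macrophages came from 4 mice in each of the 4 groups. Libraries of 3′ tags (QuantSeq) held 931496 to 7535053 counts in hepatocytes and 596380 to 5128587 in macrophages. No label gives the sex of the mice, but Xist had at least 166 counts in every library and the 4 Y-linked genes examined together at most 5, the pattern of females.

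The sequencing files fell into 2 numbered series, used here as the batch. The first series held the hepatocyte libraries of control mice 2, 7 and 8 (no CCl4) and 12 and 15 (CCl4), and the macrophage libraries of control mice 8 (no CCl4) and 11 (CCl4). Every knockout library belonged to the second series. First-series hepatocyte libraries held 4910846 to 7535053 counts and second-series ones 931496 to 2411576. Beside each count of genes, values with the series as a term and from the second series alone are therefore given. For the hepatocyte library of mouse 15 and the macrophage library of mouse 11, both after CCl4, 1 label states knockout while the genotype and group labels state control, and both were kept as controls.

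Yap1 (GRCm38, chromosome 9, 7931999 to 8004596) and Wwtr1 (chromosome 3, 57455649 to 57575910) were not called by genotype in either cell type, which does not show equal levels. In hepatocytes without CCl4 the log2 fold change of knockout over control was 0.02 for Yap1 and 0.52 for Wwtr1 (SE 0.215, adjusted p = 0.132). Wwtr1 lay between 21.6 and 43 CPM of the library total in the 5 knockout mice and between 10.4 and 19.6 in the 6 controls. The tested values are also scaled by TMM factors, 0.771 to 0.912 in these controls and 0.931 to 1.07 in these knockout mice. On that scale the ranges overlap. After CCl4 Yap1 had a log2 fold change of 0.50 (SE 0.171, adjusted p = 0.258), with 64.1 to 92.9 CPM of the library total in 4 knockout and 47.1 to 62.6 in 3 control mice. These values do not check the labels, because the deletion was directed at biliary cells, which were not sorted, and a 3′ tag can lie outside the deleted part of a gene. In knockout hepatocytes Yap1 rose with CCl4 over no CCl4 by 0.63 (SE 0.153, adjusted p = 0.00794).

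Genes of cell division rose most in hepatocytes of control livers 48 h after CCl4. All 25 measured genes of the mitosis list rose, with a median log2 fold change of 6.90, as did 23 of 25 genes of the DNA replication list (median 3.12). Genes typical of pericentral hepatocytes fell in 14 of 18 cases (median -2.46), and cholesterol synthesis genes in 21 of 23 (median -1.46). In all, 2652 of 9679 genes changed, 1324 upward and 1328 downward (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 3 against 6 mice). The even balance depended on the fit. Upward genes led with RLE factors (1445 against 1178), without a filter on low counts (1684 against 1223) and by DESeq2 (1548 against 1284), but not with the series term (1432 against 1465). With the file series as a term the count was 2897, and in the second series, which holds 1 control library after CCl4, it was 502.

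Aurkb, a mitotic kinase, had 0 counts in the 6 control libraries without CCl4 and 27.6 ± 14.2 CPM (library-scaled counts; SD, n = 3) after it, at least 147-fold higher over the group floor of 3 counts. Dlgap5, a spindle protein, was at least 109-fold higher and Prr11 at least 82.5-fold higher by the same measure. The kinetochore scaffold Knl1 and cyclin B1 (Ccnb1) had 2 counts each without CCl4, giving ratios of 535 (counting interval 148 to 4420) and 451 (124 to 3730). Such intervals, here and below, cover counting error of pooled reads and not the spread between mice. Polo-like kinase Plk1 rose by 8.31 (SE 0.970, adjusted p = 5.22e-06) and the spindle midzone gene Prc1 by 5.84 (SE 0.499, adjusted p = 6.19e-08). Ndc80, a part of the kinetochore, had 3 counts without CCl4 and a ratio of 151 (51.3 to 737). Camera called the mitosis list at adjusted p = 3.59e-26, and adjusted p = 0.102 with an estimated correlation. Among DNA replication genes, the helicase subunit Mcm2 rose by 3.67 (SE 0.374, adjusted p = 3.81e-07) and polymerase alpha subunit Pola1 by 2.60 (SE 0.253, adjusted p = 3.15e-07). Mcm10, a replication factor named after its value was seen, fell by 1.51 (SE 0.337, adjusted p = 0.00212). The replication list was called at adjusted p = 1.19e-15, and adjusted p = 0.113 with an estimated correlation, and 24 genes rose and 1 fell when adjusted over the list alone. The p53 target and cell cycle inhibitor Cdkn1a rose 10.4-fold (SE 0.424 on the log2 scale, adjusted p = 1.60e-05) and Mdm2 1.89-fold (adjusted p = 0.000466). On the p53 list 5 of 9 genes rose (camera adjusted p = 0.00167, and adjusted p = 0.137 with an estimated correlation), and adjusted over the list alone 5 rose and 1 fell.

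The glutamate transporter Slc1a2 fell by 6.67 on the log2 scale (SE 0.819, adjusted p = 5.09e-06), from 113 ± 57.7 to 0.946 ± 1.00 CPM. Glutamine synthetase (Glul), made by the hepatocytes next to the central vein, fell by 4.19 (SE 0.521, adjusted p = 1.17e-05). Cyp2e1, the main enzyme of CCl4 activation, fell by 3.93 (SE 0.605, adjusted p = 0.000130). The pericentral list was called at adjusted p = 1.11e-07, and adjusted p = 0.162 with an estimated correlation, with 15 genes lower when adjusted over the list alone. Periportal genes fell as well, in 9 of 15 cases (median -1.81), among them the urea cycle genes Ass1, which fell by 1.93, and Otc, which fell by 1.85 (SE 0.337 and 0.296, adjusted p = 0.000225 and 8.60e-05). That list had camera adjusted p = 1.85e-06, and adjusted p = 0.137 with an estimated correlation, with 11 genes lower when adjusted over the list alone. Other large decreases were in the cytochrome P450 gene Cyp2c38 (-5.38, SE 0.559), the desmosomal cadherin Dsg1c (-5.39, SE 0.564) and the melanin pathway gene Dct (-6.15, SE 1.41), with adjusted p of 1.84e-06, 2.17e-07 and 0.00244. Mup11 (-6.01, SE 1.23, adjusted p = 0.000875), whose reads can be shared with other major urinary protein genes, reached 660 CPM in control mouse 8 and at most 83.3 in the other controls without CCl4. Cyp4a12a had 2 counts after CCl4 and a ratio of 117 (32.2 to 974) without over with it, and mouse 8 held 52.2 CPM against at most 9.84 in the other controls without CCl4. Leaving out mouse 8 gave a ratio of 28.9.

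Lipid and bile acid pathways fell in the same livers. The sterol reductase gene Tm7sf2 fell 6.44-fold (SE 0.252 on the log2 scale, adjusted p = 2.19e-07) and the methylsterol oxidase gene Msmo1 6.89-fold (SE 0.459, adjusted p = 0.000205). All 23 cholesterol synthesis genes were lower when adjusted over the list alone (camera adjusted p = 1.91e-10, and adjusted p = 0.162 with an estimated correlation). Of 11 fatty acid synthesis genes 9 fell, also when adjusted over the list alone, among them Acss2, which makes acetyl-CoA (-2.55, SE 0.39). The list's camera adjusted p was 6.52e-06, and adjusted p = 0.137 with an estimated correlation. Of 12 bile acid synthesis genes 7 fell, and 8 when adjusted over the list alone, led by Slc27a5 (-2.69, SE 0.326) and sterol 27-hydroxylase, Cyp27a1 (-2.49, SE 0.374). Camera gave adjusted p = 1.85e-05, and adjusted p = 0.137 with an estimated correlation. Pro-inflammatory genes rose in 11 of 14 cases (median 2.52), including the chemokines Ccl3 (3.42, SE 0.758, adjusted p = 0.00141) and Cxcl10 (2.42, SE 0.492, adjusted p = 0.00144). Camera gave this list adjusted p = 3.65e-06, and adjusted p = 0.162 with an estimated correlation, and 11 genes rose when adjusted over the list alone. Markers of other liver cells rose with them. Of 12 stellate cell and fibroblast markers 6 rose, such as Acta2 (4.52, SE 0.776) and Pdgfrb (3.23, SE 0.607), and of 12 Kupffer cell markers 4 rose. Camera adjusted p values were 1.85e-06 and 0.00666, and adjusted p = 0.162 and 0.362 with an estimated correlation, and adjusted over the list alone the counts were 6 and 5.

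**Figure D1:**
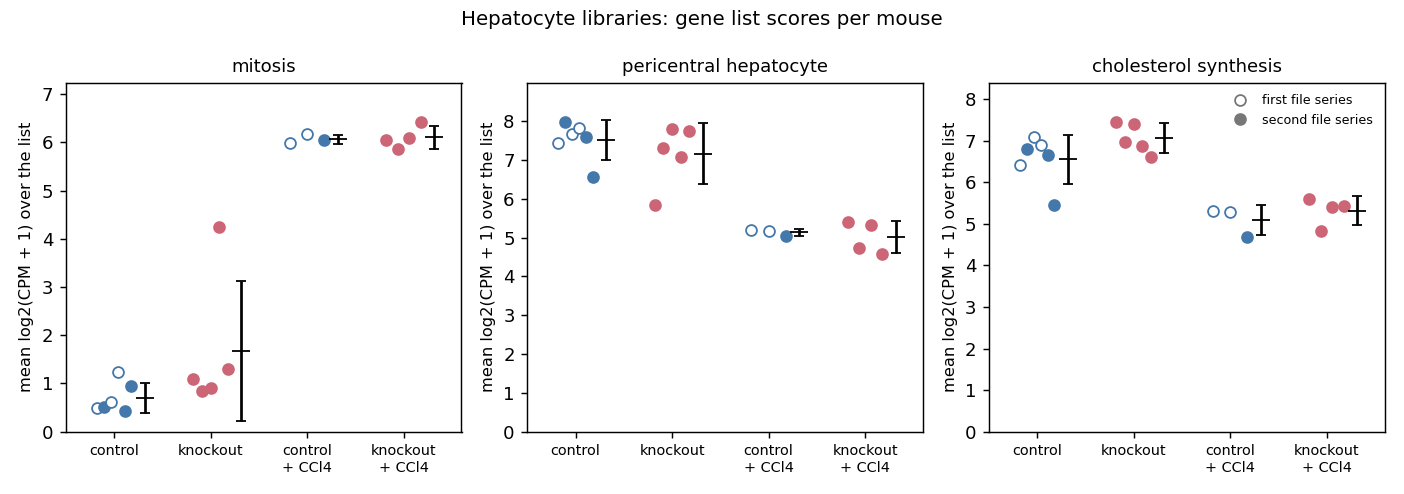
Mean log2(CPM + 1) over the genes of 3 lists (mitosis, pericentral hepatocyte and cholesterol synthesis) in each hepatocyte library, by group, with open symbols for the first file series, filled symbols for the second, and black marks for the mean ± SD of 3 to 6 mice. The mitosis mean lay at 0.702 ± 0.317 in control mice without CCl4 and 6.07 ± 0.0923 with it, and knockout mouse 20 without CCl4 stood at 4.24 while the other 4 of its group lay between 0.845 and 1.30.

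Without injury, the gene that rose most in knockout over control hepatocytes was Cib3 (chromosome 8, 72204335 to 72212837), which encodes a calcium- and integrin-binding protein. It rose 141-fold, from 1.22 ± 1.80 CPM in 6 control mice to 146 ± 40.4 in 5 knockout mice (log2 fold change 7.14, SE 0.465, adjusted p = 5.27e-09), and 6.62 in the second series alone (adjusted p = 0.000113). Also higher in knockout livers were Nid1, which encodes the basement membrane protein nidogen 1 (3.93, SE 0.424, adjusted p = 2.95e-05), the stem cell marker Prom1 (3.50, SE 0.536, adjusted p = 0.000572) and the matricellular YAP target Ccn1 (2.22, SE 0.336, adjusted p = 0.000821). Lower were the sulfotransferase Sult3a1 (-4.03, SE 0.639, adjusted p = 0.000879) and Mup12 (-6.08, SE 0.765, adjusted p = 1.72e-05). Altogether 449 genes rose and 313 fell, 762 of 9679, but with the file series as a term 61 rose and 18 fell, 79 in all, and within the second series (3 control against 5 knockout mice) 50 were called. Leaving out control mouse 2 or 8 gave 318 or 354 genes, and leaving out knockout mouse 4, 5 or 20 gave 288, 440 or 352.

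**Figure D2:**
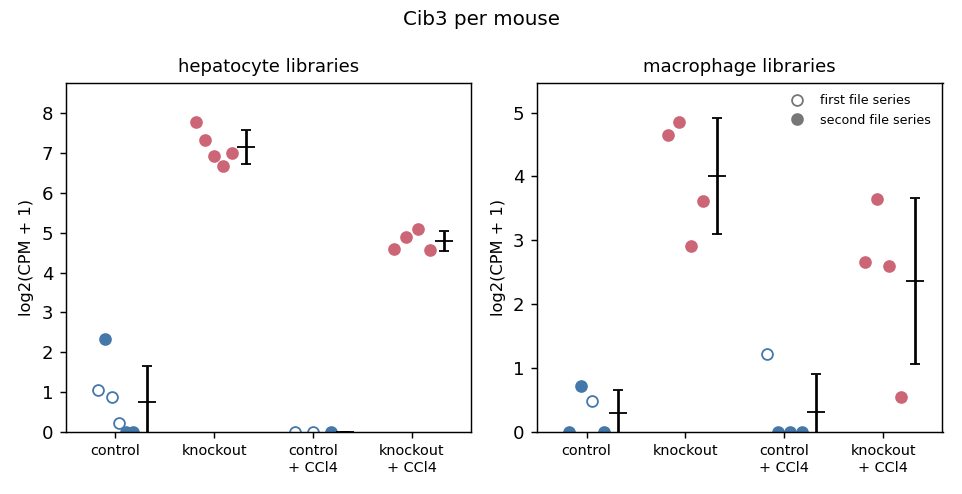
Cib3 in every library as log2(CPM + 1), with CPM of the library total, by cell type and group, open symbols for the first file series and black marks for the mean ± SD. Knockout hepatocyte libraries lay between 22.9 and 221 CPM and control ones at or below 4.04 CPM, and knockout macrophage libraries lay between 0.462 and 28 CPM and control ones at or below 1.32 CPM.

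Biliary epithelial markers were higher in knockout hepatocyte libraries for 2 of 7 genes, Prom1 and Tspan8 (2.61, SE 0.640, adjusted p = 0.0154), and for 4 when adjusted over the list alone, which adds Sox9 (1.19, SE 0.369, adjusted p = 0.0547). Camera gave adjusted p = 0.012, and adjusted p = 0.271 with an estimated correlation. YAP and TAZ targets rose in 4 of 17 cases and in 7 when adjusted over the list alone, with Tgfb2 (2.24, SE 0.559), Crim1 (1.17, SE 0.326) and the receptor Axl (2.76, SE 0.788) beside Ccn1. The list's camera result was adjusted p = 0.000234 (adjusted p = 0.271 with an estimated correlation). Of these 4 genes, Ccn1 alone was called in the second series (2.20, adjusted p = 0.000276). Scores of other liver cells were higher in the same libraries, 4.04 ± 0.915 against 2.39 ± 1.40 for stellate and 4.03 ± 0.973 against 2.98 ± 1.53 for endothelial markers (knockout against control, log2 CPM + 1, SD). Among the 5 knockout mice, mouse 4 had the highest and mouse 21 the lowest score of YAP and TAZ targets and of stellate, endothelial and Kupffer cell markers. Oxidative stress genes rose in 5 of 11 cases, and in 8 when adjusted over the list alone, such as the pentose phosphate gene Pgd (1.09, SE 0.224), Ugdh (0.92, SE 0.195) and the glutathione transferase Gsta1 (2.41, SE 0.556). For this list camera gave adjusted p = 6.54e-05, and adjusted p = 0.126 with an estimated correlation. Gstm3, another glutathione transferase, rose by 4.02 (SE 0.716, adjusted p = 0.00584), with 2580 CPM in knockout mouse 20 and at most 336 in the others of its group. Of 23 cholesterol synthesis genes 3 rose, including lanosterol synthase, Lss (1.74, SE 0.264, adjusted p = 0.000614), and Mvk (0.87, SE 0.202, adjusted p = 0.0136). On this list 4 rose when adjusted over the list alone (camera adjusted p = 0.00266, and adjusted p = 0.514 with an estimated correlation). The basolateral bile acid exporter gene Slc51b rose 4.29-fold (SE 0.394 on the log2 scale, adjusted p = 0.00410). The iron-binding acute phase protein Lcn2 rose 7.75-fold (SE 0.608, adjusted p = 0.0112), 1 of 4 genes of 21 on its list that rose (6 rose and 1 fell when adjusted over the list alone), and camera did not call that list (adjusted p = 0.0628).

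Fatty acid oxidation genes fell in 3 of 17 cases and rose in 1, and adjusted over the list alone 10 fell and 2 rose (camera adjusted p = 0.000115, and adjusted p = 0.317 with an estimated correlation). The nuclear receptor Ppara fell by 1.59 (SE 0.351, adjusted p = 0.0125), Hadha by 0.83 (SE 0.210, adjusted p = 0.0207) and Cyp4a14 by 2.37 (SE 0.624, adjusted p = 0.0327), while the hormone Fgf21 rose by 2.93 (SE 0.771, adjusted p = 0.0219). Genes with female-biased expression in mouse liver fell in 3 of 10 cases, Sult3a1 with Cyp3a44 (-3.23, SE 0.944) and Cyp2b9 (-1.40, SE 0.405), and in 4 when adjusted over the list alone, with camera adjusted p = 0.000334, and adjusted p = 0.271 with an estimated correlation. Mup11 fell by 7.44 (SE 1.26, adjusted p = 0.00127), and its control values include 660 CPM in mouse 8. The pancreatic enzyme transcripts Ctrb1 (-7.29, SE 2.14) and Prss2 (-6.94, SE 1.98) fell, and so did Pnlip and Try4, with adjusted p between 0.033 and 0.0411. Ctrb1 and Prss2 stood at 682 and 435 CPM in control mouse 6 and at most at 42.6 and 34.6 in the other controls. Pnlip and Try4 had 2 counts each in the 5 knockout libraries, with ratios of 129 (35.7 to 1070) and 98.1 (27.0 to 812), and control mouse 6 held most of the reads, with 472 of 637 and 393 of 483 counts. Leaving out mouse 6 gave ratios of 35.2 and 19.2, and Pnlip was then not called.

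Transcripts of other liver cells were also more abundant in knockout hepatocyte libraries without CCl4. Kupffer cell markers rose in 6 of 12 cases (median 2.57), with Timd4 (3.21, SE 0.655, adjusted p = 0.00573), the scavenger receptor Marco (4.43, SE 1.07, adjusted p = 0.0231) and Clec4f (2.98, SE 0.807, adjusted p = 0.0369), and in 8 when adjusted over the list alone. The mean score of these markers was 4.75 ± 1.15 in knockout and 2.98 ± 1.04 in control libraries (log2 CPM + 1, SD). Camera gave adjusted p = 4.06e-06, and adjusted p = 0.271 with an estimated correlation. With these moved the pro-inflammatory genes, 6 of 14 higher, among them Ccl3 (3.86, SE 0.738, adjusted p = 0.00293) and Tnf (3.50, SE 0.713, adjusted p = 0.00733). Adjusted over the list alone 11 were higher, with camera adjusted p = 6.65e-07, and adjusted p = 0.271 with an estimated correlation. The leukocyte tetraspanin Cd53 (4.25, SE 0.921, adjusted p = 0.00845) and the fatty acid binding protein Fabp7 (5.81, SE 1.01, adjusted p = 0.00220) rose too. Mitosis genes rose in 10 of 25 cases, and in 22 when adjusted over the list alone, with camera adjusted p = 0.0012, and adjusted p = 0.49 with an estimated correlation. Among them Bub1b and Ndc80 had 1 and 3 counts in control libraries and ratios of 34.5 (5.24 to 1460) and 14.8 (4.31 to 78.3), or 21.1 and 5.02 without knockout mouse 20. The rise of the list rests on knockout mouse 20, with a score of 4.24 where the other 4 lay between 0.845 and 1.30 and the 6 controls between 0.434 and 1.23. Without mouse 20, 0 of 25 genes were called (edgeR, 6 at unadjusted p under 0.05) and the median went from 2.83 to 0.59. Leaving out mouse 2, 7, 8, 9 or 10 gave 2, 4, 3, 5 or 16.

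After CCl4, knockout and control hepatocytes differed in few genes. Cib3 had 0 counts in the 3 control libraries, including that of mouse 15 with the conflicting label, and 22.7 ± 5.24 CPM in 4 knockout mice, at least 100-fold higher over the group floor of 3 counts (adjusted p = 3.66e-05). The keratin gene Krt23 (chromosome 11, 99477974 to 99493137), a marker of biliary cells, rose 9.05-fold from 3.10 ± 2.29 to 29.6 ± 10.6 CPM (SE 0.515 on the log2 scale, adjusted p = 0.00865). The actin bundler Pls1 rose by 2.47 (SE 0.400, adjusted p = 0.00865), the oxysterol binding protein Osbpl3 by 2.89 (SE 0.529, adjusted p = 0.0120), the membrane protease Mmp15 by 1.85 (SE 0.322, adjusted p = 0.0120) and Tspan8 by 2.58 (SE 0.539, adjusted p = 0.0374). In total 17 genes changed, 12 upward and 5 downward, by edgeR's quasi-likelihood test. With the series as a term 3 were called and in the second series, with 1 control library, 1. Without the mouse with the conflicting label, mouse 15, 4 genes were called, and with that library moved to the knockout group 0 were called by edgeR, where 1241 had unadjusted p under 0.05 with it kept as control. DESeq2 called 50 and limma voom 49, and fits of the contrast's own groups called 24 upward and 26 downward, so the upward majority depends on the fit. Omitting control mouse 12 or 16 gave 5 or 130 genes and omitting knockout mouse 17 gave 5.

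The 5 genes that fell were Saa3 (chromosome 7, 46711998 to 46715700), an acute phase serum amyloid gene (-3.95, SE 0.747, adjusted p = 0.0482), and Hist1h2ao (-3.55, SE 0.598), a histone whose near-identical copies can share reads, with the smooth muscle gene Tagln (-2.97, SE 0.585), the sulfotransferase Sult5a1 (-2.34, SE 0.426) and the co-chaperone Dnajc12 (-2.05, SE 0.356). Saa3 was called in 4 of 18 fits that each left out 1 library, and Tspan8 in 10. The other serum amyloid genes of the list, Saa1 (-3.74, SE 0.899, adjusted p = 0.147) and Saa2 (-4.46, SE 1.15, adjusted p = 0.169), passed only when adjusted over the list alone. Of 21 acute phase genes 1 was lower over all genes and 4 when adjusted over the list alone, and camera gave adjusted p = 0.00021 (adjusted p = 0.629 with an estimated correlation). Of 7 biliary markers 2 rose, and 4 when adjusted over the list alone, where Krt19 (2.47, SE 0.633, adjusted p = 0.147 over all genes) and Prom1 (1.66, SE 0.468, adjusted p = 0.178) joined Krt23 and Tspan8. Camera gave that list adjusted p = 2.14e-05, and adjusted p = 0.0647 with an estimated correlation. The 2 basolateral exporters measured passed only when adjusted over the list alone, Slc51b (1.94, SE 0.464) and Abcc3 (1.04, SE 0.233). On the DNA replication list 0 of 25 genes passed over all genes (edgeR) and 3 were lower when adjusted over the list alone, such as Pola1 (-1.30, SE 0.271, adjusted p = 0.0535), with camera adjusted p = 0.00021 and adjusted p = 0.629 with an estimated correlation. On the interferon list 0 of 14 passed over all genes (edgeR) and 5 were lower when adjusted over the list alone, with Gbp3 at -1.29 (SE 0.342), camera adjusted p = 0.000519 and adjusted p = 0.341 with an estimated correlation. Scores of other cells were lower in the same libraries, 5.15 ± 0.71 in control and 3.92 ± 0.508 in knockout mice for stellate, 4.22 ± 0.596 and 3.28 ± 0.397 for endothelial markers, and 4.85 ± 0.253 and 3.98 ± 0.562 for pro-inflammatory genes.

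The genotype effects without and after CCl4 shared 9 hepatocyte genes, 8 higher (BC005561, Cib3, Krt8, Mmp15, Ocln, Osbpl3, Pls1 and Tspan8) and 1 lower (Sult5a1) in knockout livers both times, where independent lists of these sizes would share 0.557 and 0.162. Krt8, a keratin of simple epithelia, rose by 1.52 (SE 0.214, adjusted p = 0.000271) without and 1.35 (SE 0.269, adjusted p = 0.0374) after CCl4, and the tight junction gene Ocln by 0.83 (SE 0.240, adjusted p = 0.0383) and 1.67 (SE 0.310, adjusted p = 0.0178). Shared genes outside the naming rule were named after their values were seen. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson correlation of 0.322, 0.258 with the series as a term, and 0.0452 in the second series, where the comparison after CCl4 rests on 1 control library and a low value is no test. With the series as a term both comparisons called 1 gene in common. The 2 comparisons have no library in common, but all first-series libraries were controls in both, so the file series could move both alike.

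In knockout livers CCl4 again raised genes of division, and all 25 mitosis genes rose (median 4.08). Examples are Nusap1, which bundles spindle microtubules (4.38, SE 0.581, adjusted p = 5.29e-05), and Prc1 (4.02, SE 0.483, adjusted p = 2.52e-05). Kif20a, a mitotic kinesin, had 2 counts without CCl4 and a ratio of 40.5 (10.8 to 341). The fetal liver gene Afp rose 23.0-fold (SE 0.414 on the log2 scale, adjusted p = 1.66e-06), the kinetochore gene Kntc1 22.2-fold (SE 0.669) and the noncoding RNA Lockd 29.2-fold (SE 0.582). Falling most were Slc1a2 (-6.62, SE 0.889), the hepcidin gene Hamp2 (-5.81, SE 1.06), whose reads can be shared with Hamp, the sulfotransferase Sult2a1 (-4.82, SE 0.834) and Glul (-4.50, SE 0.479). A total of 1341 genes changed, 679 upward and 662 downward, 1520 with the series as a term and 1245 in the second series, and 751 without knockout mouse 18. The mitosis list kept its call with an estimated correlation (camera adjusted p = 7.13e-36, and adjusted p = 0.0282 with an estimated correlation). Cholesterol synthesis genes fell in 22 of 23 cases and in all 23 when adjusted over the list alone, with Idi1 (-3.12, SE 0.425) and Fdft1 (-2.21, SE 0.277) as examples (camera adjusted p = 4.66e-20, and adjusted p = 0.1 with an estimated correlation). Acute phase genes fell in 10 of 21 cases, and in 13 when adjusted over the list alone, among them the haptoglobin gene Hp (-1.36, SE 0.255) and hemopexin, Hpx (-1.36, SE 0.265), with camera adjusted p = 7.81e-08, and adjusted p = 0.115 with an estimated correlation.

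The response to CCl4 itself differed by genotype for 21 genes in hepatocyte libraries, 2 with a more positive and 19 with a more negative response in knockout livers. Krt23 (interaction 3.98, SE 0.657, adjusted p = 0.0358) and the transporter Abca8a (1.61, SE 0.334, adjusted p = 0.0452) were the 2 positive ones. More negative were Fabp7 (-6.78, SE 1.37), the macrophage elastase Mmp12 (-5.96, SE 1.20), the interferon-induced Ifi27l2a (-4.67, SE 0.949), the complement receptor C3ar1 (-4.07, SE 0.764) and Ccl3 (-4.72, SE 1.02), with adjusted p between 0.0358 and 0.0452. Pro-inflammatory genes were called in 1 of 14 cases, and in 11 when adjusted over the list alone, where Tnf (-4.72, SE 1.02, adjusted p = 0.0511 over all genes) passes, with camera adjusted p = 9.25e-15, and adjusted p = 0.109 with an estimated correlation. Kupffer cell markers, which move with these genes, had a median interaction of -3.01, with 0 of 12 called over all genes (edgeR) and 8 when adjusted over the list alone, and camera adjusted p = 8.17e-09, and adjusted p = 0.145 with an estimated correlation. The Kupffer cell score of these hepatocyte libraries was 2.98 ± 1.04 in control and 4.75 ± 1.15 in knockout mice without CCl4. After CCl4 it was 4.39 ± 0.061 and 3.93 ± 0.388. Whether RNA of macrophages in the libraries gave the negative calls was not tested. The series term gave 54 genes. In the second series, where 1 control library after CCl4 leaves little power, edgeR called 0, and 0 was also the count after thinning all libraries to the smallest total. From all libraries DESeq2 called 46, voom 6, and 987 genes had unadjusted p under 0.05. The count fell to 0 without mouse 2, 8, 4, 5, 16, 13, 14 or 17, and was 3, 2, 4 or 8 without mouse 9, 15, 18 or 20. It was 41, 63, 68, 93 or 38 without mouse 7, 19, 10, 21 or 12.

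In macrophages of control livers, CCl4 raised genes of division, genes of lipid-associated macrophages and monocyte markers, and lowered Kupffer cell markers. Mitosis genes rose in 23 of 24 cases (median 3.65), DNA replication genes in 20 of 24 (median 1.99), lipid-associated macrophage markers in 9 of 13 (median 1.99) and monocyte markers in 8 of 14 (median 1.78), while Kupffer cell markers fell in 6 of 13 (median -1.08). In all 1423 of 10815 genes changed, 732 upward and 691 downward (4 against 4 mice), 1440 with the series as a term and 867 in the second series. The balance turned with the hepatocyte transcript score as a term, to 679 upward and 944 downward, and without a filter on low counts, to 880 and 1164. Omitting control mouse 15 or 16 after CCl4 gave 935 or 903. Alb, the albumin gene of hepatocytes, made up 229 to 21200 CPM of the macrophage libraries and was lowest in these 2 mice.

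Among division genes, the checkpoint kinase Bub1 rose by 4.89 (SE 0.528, adjusted p = 1.06e-05), topoisomerase Top2a by 3.71 (SE 0.39, adjusted p = 2.48e-05), the kinetochore genes Ttk by 3.72 (SE 0.462) and Ndc80 by 3.05 (SE 0.354). The kinesin Kif2c rose by 5.02 (SE 0.862) and cyclin E1, Ccne1, by 4.76 (SE 0.790). Ska1 had 2 counts without CCl4 and a ratio of 54.5 (14.7 to 457). On the replication list Rrm1, a ribonucleotide reductase subunit (2.79, SE 0.274), and the ligase Lig1 (2.78, SE 0.350) led. The mitosis and replication lists had camera adjusted p = 1.53e-23 and 3.74e-15, and adjusted p = 0.0809 and 0.132 with an estimated correlation, and 24 and 23 genes rose when adjusted over the list alone. The lipid chaperone Fabp5 rose 12.9-fold (SE 0.507 on the log2 scale, adjusted p = 0.000195), the tetraspanin Cd63 7.12-fold (SE 0.395), lipoprotein lipase Lpl 5.27-fold (SE 0.384) and the integrin Itgax 8.58-fold (SE 0.498). On this list Apoe, named after its value was seen, fell by 1.56 (SE 0.336, adjusted p = 0.00524). Camera gave adjusted p = 2.02e-07, and adjusted p = 0.0809 with an estimated correlation, and adjusted over the list alone 11 rose and 1 fell. The growth factor gene Gdf3 rose 28.7-fold (SE 0.599, adjusted p = 4.37e-05), and Cyp4f18 had 2 counts without CCl4 and a ratio of 38.7 (10.3 to 326).

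Monocyte genes that rose included the chemokine receptors Ccr2 (2.82, SE 0.509) and Cx3cr1 (2.78, SE 0.489), Ly6c2 (2.15, SE 0.39) and the coagulation factor F13a1 (3.09, SE 0.509), with adjusted p between 0.000745 and 0.00202. The list's camera adjusted p was 0.000155, and adjusted p = 0.0809 with an estimated correlation, and 9 rose and 1 fell when adjusted over the list alone. Of Kupffer cell genes, complement C6 fell by 2.84 (SE 0.373, adjusted p = 0.000108), ficolin A, Fcna, by 2.11 (SE 0.384, adjusted p = 0.00160), Cdh5 by 1.08 (SE 0.277, adjusted p = 0.0151) and Timd4, a receptor for dying cells, by 1.54 (SE 0.411, adjusted p = 0.0204). On this list 9 were lower when adjusted over the list alone. Sinusoidal endothelial markers were lower in the same libraries, with a score of 7.10 ± 0.284 without and 5.48 ± 1.36 with CCl4. For Kupffer cell markers camera gave adjusted p = 2.80e-05, and adjusted p = 0.485 with an estimated correlation. Immediate early genes fell in 7 of 13 cases, and in 11 when adjusted over the list alone, among them Egr1 (-1.21, SE 0.208) and the phosphatase Dusp1 (-1.48, SE 0.265), with camera adjusted p = 1.06e-07, and adjusted p = 0.0809 with an estimated correlation. The cytokines Il6 (-2.74, SE 0.418, adjusted p = 0.000411) and Il1b (-1.12, SE 0.269, adjusted p = 0.0110) fell, 2 of 3 pro-inflammatory genes of 16 that did. Adjusted over the list alone 5 fell and 2 rose (camera adjusted p = 0.019, and adjusted p = 0.579 with an estimated correlation). Large decreases were in transcripts more abundant in hepatocyte than in macrophage libraries: Sult2a8 (-5.81, SE 0.573), Cyp2e1 (-5.38, SE 0.892) and Thrsp (-5.36, SE 0.949). Cyp2c54 and Cyp2c38, of the same kind, had 2 and 1 counts after CCl4 and ratios of 143 (39.2 to 1180) and 163 (28.9 to 6470) without over with it. Gdpd3, a phosphodiesterase gene higher in macrophage libraries, fell by 5.52 (SE 1.19, adjusted p = 0.00452). Hepatocyte identity genes had a median of -1.49, with 0 of 16 called over all genes (edgeR) or adjusted over the list alone, camera adjusted p = 2.11e-05, and adjusted p = 0.485 with an estimated correlation.

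**Figure D3:**
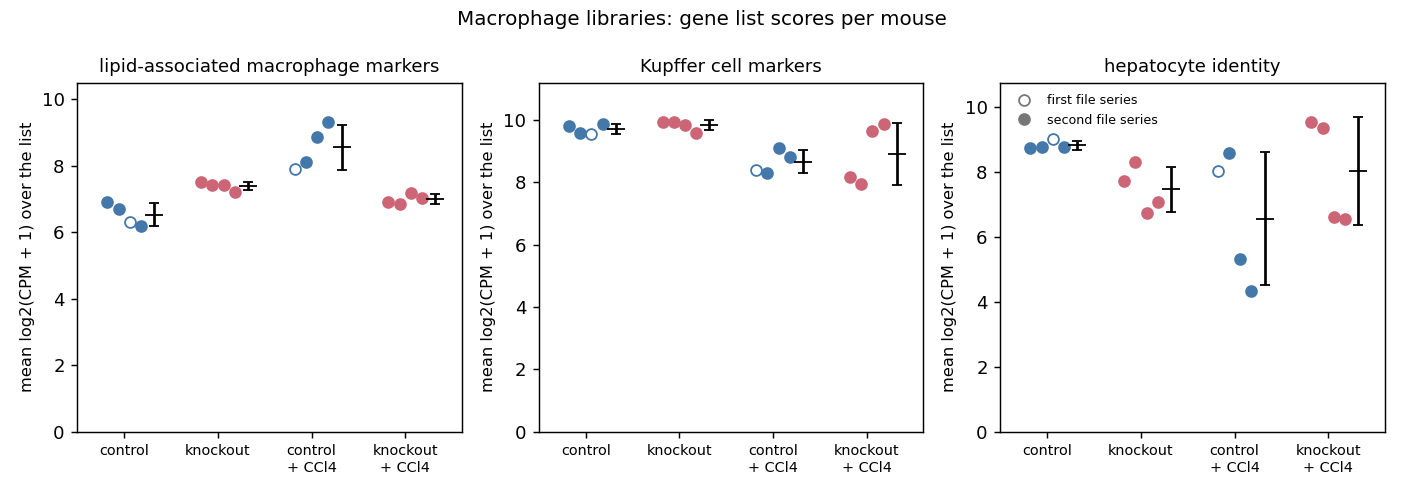
Mean log2(CPM + 1) over 3 lists (lipid-associated macrophage, Kupffer cell and hepatocyte identity genes) in each macrophage library, by group, with open symbols for the first file series and black marks for the mean ± SD of 4 mice. Lipid-associated genes lay at 8.55 ± 0.665 in control and 6.99 ± 0.153 in knockout mice after CCl4, and hepatocyte identity genes ranged from 4.34 to 8.57 and from 6.55 to 9.54 in those groups.

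Without injury, macrophage libraries of knockout livers differed from controls in 18 genes, 6 higher and 12 lower. Hepatocyte RNA in these libraries was not told apart from expression by macrophages. With the hepatocyte transcript score as a term 14 of the 18 stayed called in the same direction (edgeR). Higher were Cib3, with 3 counts in control libraries and a ratio of 51.9 (17.3 to 255), and the chemokine receptor Cx3cr1 (2.65, SE 0.489, adjusted p = 0.0318). So were the adaptor Stap1 (2.49, SE 0.452, adjusted p = 0.0257), the leukocyte actin-binding protein Lsp1 (1.59, SE 0.295, adjusted p = 0.0284), the mitochondrial carrier Slc25a24 (1.45, SE 0.263, adjusted p = 0.0257) and the scavenger receptor Cd36 (1.28, SE 0.242, adjusted p = 0.0318). Cib3 alone of the 6 was more abundant in hepatocyte than in macrophage libraries. In knockout mice without CCl4 it stood at 146 ± 46.8 CPM of the library total in hepatocytes and 17.4 ± 10.2 in macrophages, where Alb stood at 54300 to 69300 and 2750 to 9080 CPM. Of the 12 lower genes 11 were more abundant in hepatocyte than in macrophage libraries, and all 12 had lower values in knockout hepatocytes as well. The mice of these macrophage libraries also gave hepatocyte libraries, so the likeness is not independent. The lower genes include Sult2a8 (-6.04, SE 0.593, adjusted p = 5.62e-07), the bile acid 12-hydroxylase Cyp8b1 (-4.26, SE 0.657, adjusted p = 0.00496) and Cyp2c54 (-3.95, SE 0.676, adjusted p = 0.0119). Others are Sult5a1 (-4.88, SE 0.968, adjusted p = 0.0257) and Ces3a (-5.25, SE 0.996, adjusted p = 0.0447). Sult3a1 had 2 counts in knockout libraries and a ratio of 64.5 (17.6 to 536) of control over knockout. The mean score of hepatocyte identity genes was 8.81 ± 0.136 in control and 7.45 ± 0.699 in knockout macrophages. Of its 16 genes 0 were called over all genes (edgeR) or adjusted over the list alone (camera adjusted p = 4.15e-05, and adjusted p = 0.471 with an estimated correlation). In hepatocytes Cyp8b1 itself did not pass (-1.86, SE 0.974, adjusted p = 0.245), and its values were split within the knockout group. It stood at 1.03, 5.09 and 3.7 CPM in knockout mice 4, 5 and 20 and at 125 and 234 in knockout mice 10 and 21. Controls lay between 152 and 382 CPM.

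Lipid-associated markers passed in 0 of 13 cases over all genes (edgeR) and in 6 when adjusted over the list alone, all higher in knockout macrophages, among them Ctsd (1.08, SE 0.295), Lpl (1.27, SE 0.371), Cd63 (1.29, SE 0.384) and galectin 3, Lgals3 (1.14, SE 0.373). Their adjusted p over all genes lay between 0.13 and 0.222, with camera adjusted p = 4.42e-05, and adjusted p = 0.333 with an estimated correlation. Stellate cell and fibroblast markers were higher in the same libraries, with a score of 5.74 ± 1.01 in knockout and 4.18 ± 0.421 in control mice. Mitochondrial transcripts made up 6.94% to 15.9% of counts in these knockout and 14.7% to 24.7% in these control libraries. The score of immediate early genes was 9.73 ± 0.245 in knockout and 10.3 ± 0.131 in control mice. The count of 18 was 34 with the series as a term and 19 in the second series, and higher genes made up 33.3% of calls with TMM scaling, 46.4% with RLE factors and 48.1% without mitochondrial transcripts. The balance turned with the hepatocyte transcript score as a term, to 115 higher and 68 lower, and with the series as well, to 177 and 121, while fits of the contrast's own groups gave 57 higher and 200 lower. Control mice 6 and 7, knockout mice 4 and 20 without CCl4, and knockout mice 14 and 18 with it moved the count to 6, 11, 1, 7, 31 and 50 when left out.

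After CCl4, lipid-associated macrophage markers were lower in macrophages of knockout than of control livers. Of 13 measured genes 1 passed over all genes, the proton pump subunit Atp6v0d2 (-3.30, SE 0.611, adjusted p = 0.0479), while adjusted over the list alone 10 were lower and 1, Apoe, was higher (1.12, SE 0.333, adjusted p = 0.355 over all genes), with a median of -1.82. Gpnmb, a transmembrane glycoprotein (chromosome 6, 49036546 to 49070929), stood at 495 ± 313 CPM in 4 control and 27.5 ± 13.4 in 4 knockout mice (-4.24, SE 0.799, adjusted p = 0.0983). Fabp5 stood at 144 ± 68.7 and 28.2 ± 14.6 (-2.35, SE 0.477, adjusted p = 0.104) and Lgals3 at 1440 ± 635 and 406 ± 235 (-1.83, SE 0.380, adjusted p = 0.108). The list kept its call with an estimated correlation (camera adjusted p = 6.34e-13, and adjusted p = 0.0210 with an estimated correlation), and its median was -1.92 with the series as a term and -1.96 in the second series.

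Of 14 monocyte markers 0 passed over all genes (edgeR) and 5 were lower when adjusted over the list alone, with S100a4 (-2.12, SE 0.474), Ly6c2 (-1.68, SE 0.388) and F13a1 (-2.06, SE 0.489) first (camera adjusted p = 2.86e-06, and adjusted p = 0.0210 with an estimated correlation). Over all genes 7 were called, 1 higher and 6 lower, but without a filter on low counts 286 were higher and 106 lower. Dmbt1, a secreted scavenger receptor protein, rose by 3.45 (SE 0.613, adjusted p = 0.0446). Dmbt1 and Apoe were more abundant in hepatocyte than in macrophage libraries of controls without CCl4 (13.4 against 6.61 and 16100 against 7990 CPM). The hepatocyte identity score was 8.01 ± 1.66 in these knockout and 6.56 ± 2.06 in these control macrophages. The cytokine receptor Il7r fell by 2.46 (SE 0.392, adjusted p = 0.0329), the signalling protein Malt1 by 2.00 (SE 0.332, adjusted p = 0.0351), Emp1 by 1.96 (SE 0.303, adjusted p = 0.0329) and the myosin Myo5a by 1.90 (SE 0.322, adjusted p = 0.0351). The series term gave 6 genes, and edgeR called 0 in the second series and 0 with the library of the conflicting label, mouse 11, moved to the knockout group, against 39 by DESeq2 and 3 by voom from all libraries and 871 genes at unadjusted p under 0.05. The count fell to 0 without mouse 9, 15, 16, 13, 17 or 18, to 4 without mouse 5 and to 3 without mouse 14.

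In knockout livers CCl4 changed 95 macrophage genes, 83 upward and 12 downward. Count and balance depended on the fit. The contrast's own groups gave 12 upward and 2 downward, the hepatocyte transcript score as a term 159 and 117, and no filter on low counts 288 and 143. Mitosis genes rose in 13 of 24 cases and in all 24 when adjusted over the list alone (median 2.31), and the list kept its call with an estimated correlation (camera adjusted p = 8.50e-47, and adjusted p = 0.00694 with an estimated correlation). Ttk rose by 3.01 (SE 0.440, adjusted p = 0.00362), Prc1 by 2.54 (SE 0.367, adjusted p = 0.00367), Top2a by 2.45 (SE 0.368, adjusted p = 0.00505) and the proliferation marker Mki67 by 1.80 (SE 0.294, adjusted p = 0.00846). Of 24 replication genes 6 rose, and 22 when adjusted over the list alone, with Ccne1 (3.19, SE 0.622, adjusted p = 0.0140) among them (camera adjusted p = 2.54e-24, and adjusted p = 0.114 with an estimated correlation). The repair gene Rad54b (3.62, SE 0.564), the transcription factor Mybl1 (3.40, SE 0.607) and Ly6d (3.52, SE 0.752) rose as well. The chemokine Ccl24 (-2.06, SE 0.424), glutathione reductase, Gsr (-1.97, SE 0.344), the purinergic receptor P2ry13 (-1.57, SE 0.355) and H2-K2 (-1.51, SE 0.321), whose reads can be shared with other class I genes, fell. The count was 109 with the series as a term and 95 in the second series. It was 34, 18 or 20 without mouse 4, 5 or 21 and 54 or 33 without mouse 14 or 18.

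The macrophage response to CCl4 differed by genotype for 21 genes, 7 with a more positive and 14 with a more negative response in knockout livers. Lipid-associated markers were called in 4 of 13 cases, all negative: Lpl (-2.98, SE 0.527, adjusted p = 0.0227), Lgals3 (-2.96, SE 0.532, adjusted p = 0.0227), Fabp5 (-3.86, SE 0.694, adjusted p = 0.0253) and Gpnmb (-6.04, SE 1.08, adjusted p = 0.0420). Adjusted over the list alone 10 were negative, and the call held with an estimated correlation (camera adjusted p = 3.80e-12, and adjusted p = 0.0256 with an estimated correlation). Gdf3 (-5.47, SE 0.823, adjusted p = 0.00431) and Syngr1 (-5.06, SE 1.06, adjusted p = 0.0445) were also negative. Monocyte markers were called in 1 of 14 cases, F13a1 (-3.58, SE 0.709, adjusted p = 0.0445), and adjusted over the list alone in 8 negative cases and 1 positive, with camera adjusted p = 2.50e-06, and adjusted p = 0.0256 with an estimated correlation. The positive genes include the hepatocyte transcripts Cyp2c54 (7.85, SE 1.34), Sult2a8 (7.15, SE 1.13), Cyp8b1 (5.72, SE 1.07) and Mettl7a1 (2.97, SE 0.531), with adjusted p between 0.00357 and 0.0227. Hepatocyte identity genes had a median interaction of 2.52, with 0 of 16 called over all genes (edgeR) and 1 when adjusted over the list alone (camera adjusted p = 7.08e-09, and adjusted p = 0.458 with an estimated correlation). The count of 21 was 17 with the series as a term and 7 in the second series, and positive genes made up 33.3% of calls, or 16.7% after thinning to the smallest total. The balance turned with DESeq2, to 82 positive and 70 negative, and without a filter on low counts, to 535 and 162. Leaving out mouse 12 or 18 gave 94 or 111 genes, and leaving out mouse 9, 4, 15, 16, 13 or 14 gave 11, 10, 11, 12, 13 or 12.

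In macrophages no gene was called for the genotype both without and after CCl4 by edgeR, where 171 genes had unadjusted p under 0.05 in both comparisons, 39 of them higher and 21 lower both times against 28.0 and 23.9 for independent lists. The Pearson correlation across genes of the 2 sets of log2 fold changes was -0.127. With the series as a term the sign turned, with a correlation of 0.0768, and 110 genes were higher and 39 lower both times at unadjusted p, against 44.1 and 29.6. In the second series the correlation was -0.012, with 66 higher and 31 lower against 47.6 and 30.4.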

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

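Chosen only after the result was seen were the tests of the file series as part of the cause, of depth, list medians with the series or the hepatocyte score as a term, and all values from the second series alone or after thinning. A batch term for counts of genes was set beforehand, and the series was chosen as that batch on reading the sample tables.

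The 762 genes called between knockout and control hepatocytes without CCl4 were weighed against the file series, which holds 3 of the 6 controls and no knockout mouse, and against depth. Against the series as the whole cause, 500 genes picked from 3 knockout mice over first-series controls went the same way in the other 2 knockout mice over second-series controls in 73.8% of cases at the lowest of 10 picks, a bound that was lenient, since 59.0% to 64.9% of all genes did so and RNA of other cells may be shared between the picks and the test. The folds were much smaller there. Over the 10 picks, the median log2 size of the picked genes was 1.20 to 1.42 where they were picked and 0.209 to 0.442 in the other libraries. The series may be part of the cause: with it as a term 79 genes were called, 72 of the 762 among them, the median size of the 762 going from 1.29 (median SE 0.308) to 1.02 (0.344) with 760 in the same direction, so that calls ended through smaller folds and wider errors. On depth, thinning every library to the smallest total left the 677 of the 762 genes still measured in the same direction, with a median size of 1.10 (median SE 0.319). Then 303 genes were called, since thinning also removes power, and the bound was set after these values were seen. Thinning draws from the same counts that picked these genes, so direction and size were largely given beforehand. Genes no longer measured are not covered, and depth as a cause is not excluded. A response of hepatocytes to the loss of YAP and TAZ in bile ducts stays open as a hypothesis, with Cib3 called in each of these settings. RNA of other cells was not weighed as a cause for the 762 genes. Kupffer and stellate cell scores were higher in the same knockout libraries (4.75 ± 1.15 against 2.98 ± 1.04 and 4.04 ± 0.915 against 2.39 ± 1.40). Upward calls may therefore be of transcripts from those cells.

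Kupffer cell transcripts were higher in hepatocyte libraries of knockout mice without CCl4, with a list median of 2.57. Against the file series as the whole cause, the median with it as a term was 2.24. RNA of non-parenchymal cells in the hepatocyte libraries may be a cause. Of 170 other abundant transcripts at least 50 times higher in macrophage libraries than in control hepatocyte libraries without CCl4, 99.4% were higher in knockout libraries (169, median 2.14). They were picked for low values in the same controls that the knockout libraries were then compared with. The pick itself favours a rise, so this share does not decide the question. Percoll separation and the exclusion of dead cells by propidium iodide are steps meant to remove such cells, but not RNA or fragments bound to hepatocytes. Whether knockout livers held more macrophages, or hepatocytes were less well separated from them, was not tested.

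Lipid-associated macrophage markers were lower in macrophages of knockout livers after CCl4, with a list median of -1.82. Dilution by RNA of other cells would lower macrophage transcripts alike, but 252 other macrophage transcripts had a lower quartile of -0.39, above that median. That set was picked by abundance in macrophage libraries without CCl4 and may hold transcripts of endothelial and stellate cells. Their scores were higher in knockout than in control libraries after CCl4 (6.56 ± 0.667 against 5.48 ± 1.36 and 6.00 ± 1.31 against 4.68 ± 1.80). Such RNA could raise part of the set, so dilution by these cells is not excluded. In the second series the list median was -1.96, and it was -1.96 without the library whose labels conflict, but both settings leave out mouse 11 and are not independent of each other. Hepatocyte RNA alone does not account for it, since the median was -1.26 with the hepatocyte score as a term, and knockout mice 17 and 18, with hepatocyte scores of 6.60 and 6.55, had list scores of 7.18 and 7.04, below the 7.90 and 8.10 of control mice 11 and 12 with hepatocyte scores of 8.02 and 8.57. A smaller share of lipid-associated macrophages, or lower expression in each, may underlie the pattern, which was found and tested on the same data, and no sort separated these cells.

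Other splits of the same mice into groups of the same sizes were refitted for every comparison. In hepatocytes the real split alone reached its count for CCl4 in controls (1 of 84 splits, 2652 genes, highest other 587), and for CCl4 in knockout mice (1 of 100, 1341, 898), so chance is unlikely there but not excluded. For the knockout without CCl4 it was 1 of 100 (762, 430), but all first-series libraries were controls, so these splits do not part genotype from the file series. For the knockout after CCl4 it was 1 of 35 (17, 15), but a margin of 2 genes is too small to rest on, with 5, 4 or 5 genes called without mouse 12, 15 or 17, and the series is not parted from genotype there either. For the interaction 3 of 100 splits reached 21, the highest other 101. Within the second series 2 of 56 splits reached the 50 genes of the knockout without CCl4, and the other split, mice 6, 9, 10, 19 and 21 against 4, 5 and 20, called 229, which points to a structure of the samples beside genotype, so chance is not taken as excluded for that count. In macrophages 1 of 35 splits reached the counts for CCl4 in controls (1423, 13), the knockout without CCl4 (18, 1) and CCl4 in knockout mice (95, 4), and 2 of 100 that for the interaction (21, 672). For the knockout after CCl4 in macrophages 3 of 35 splits reached 7 genes, so chance is not excluded. The highest other, mice 15, 16, 17 and 18 against 11, 12, 13 and 14, called 1834, a structure of the samples that runs with Alb of 229 to 1977 against 4221 to 21211 CPM and holds 2 mice of each genotype on each side, so these splits measure chance for the genotype poorly.

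Single libraries that stood apart from the rest of their group are listed with their value in CPM and the nearest other of the group, for groups of 4 to 6 mice and genes the text names. Chance would single out about 1 in 20 groups of values, and 84 of 584 (14.4%) were, on the CPM scale, which stretches high values. On a log2 scale, tried later, 48 instead of 82 gene values were. For 14 of the 82 no library of the group held more than 3 counts, so these libraries do not stand apart: in hepatocytes Bub1b, Ccnb1, Fabp7, Kif20a, Knl1 and Kntc1 (controls without CCl4) and Kif20a, Kntc1 and Mup12 (knockout mice without CCl4), and in macrophages Kif2c, Ska1, Cyp2c38 and both values of Sult3a1. The library of mouse 8 also had the largest total among control macrophages without CCl4 (5130000, next 1720000), and that of mouse 18 the lowest Alb among knockout hepatocytes after CCl4 (53600, next 60500).

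Among control hepatocytes without CCl4, such libraries were mouse 19 for BC005561 (63.7, 43.5), Cd53 (5.3, 1.17), Marco (23.3, 8.22), Mmp12 (6.37, 2.35) and Saa3 (127, 55.4), and mouse 7 for Bub1b (0.205, 0) and Kntc1 (0.205, 0). Mouse 6 for Ccl3 (4.69, 1.06), Cib3 (4.69, 1.39), Ctrb1 (682, 42.6), Fabp7 (3.52, 1.06), Pnlip (554, 29.1), Prss2 (435, 34.6), Tnf (7.04, 2.05) and Try4 (461, 18.2), and mouse 8 for Ccnb1 (0.425, 0), Cyp4a12a (52.2, 9.84), Knl1 (0.425, 0), Lockd (1.49, 0.52), Mup11 (660, 83.3) and Plk1 (0.849, 0.205). Mouse 9 for Fgf21 (3.61, 1.27), Lcn2 (318, 53.9) and Saa2 (1650, 610), and mouse 2 for Kif20a (0.173, 0). Among knockout hepatocytes without CCl4, such libraries were mouse 20 for Aurkb (9.62, 1.03), Ccnb1 (15.5, 2.57), Gsta1 (25.2, 8.66), Gstm3 (2580, 336), Knl1 (11.8, 1.27), Kntc1 (2.22, 0.637), Krt8 (210, 130), Lockd (4.44, 0.637), Ndc80 (9.62, 1.44), Nusap1 (19.2, 0.857), Plk1 (28.9, 0.637), Prc1 (13.3, 4.28) and Prr11 (2.96, 0.857), and mouse 10 for BC005561 (152, 116) and Kif20a (1.44, 0). Mouse 21 for Ctrb1 (3.43, 0.722), Cyp3a44 (3.43, 0.722), Cyp4a12a (4.28, 0.514), Mup11 (4.28, 0.722), Mup12 (2.57, 0.722) and Sult3a1 (30.8, 7.22). Among knockout hepatocytes after CCl4, such libraries were mouse 13 for Acss2 (48.1, 24.4), Cyp3a44 (11.4, 0.938) and Prom1 (48.1, 62.3), and mouse 17 for Cdkn1a (111, 146) and Pnlip (14.1, 0.774). Mouse 14 for Cyp4a12a (6.2, 0.663), and mouse 18 for Marco (22.5, 9.38), Mmp12 (4.31, 0.938) and Slc1a2 (1.66, 0).

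Among control macrophages without CCl4, such libraries were mouse 8 for Ccne1 (1.1, 0) and Ska1 (0.441, 0), and mouse 7 for Ctsd (586, 796), Itgax (0, 12.1) and Myo5a (15.9, 11.2). Mouse 6 for Fcna (1580, 1270), Lpl (1490, 638) and Ndc80 (8.72, 5.18), and mouse 9 for Kif2c (2.59, 0.22). Among knockout macrophages without CCl4, such libraries were mouse 4 for Gdpd3 (20.6, 2.05), S100a4 (54.7, 26.6) and Syngr1 (16, 3.24), and mouse 20 for Gsr (55, 98.3) and Top2a (173, 60.5). Mouse 5 for Sult3a1 (2.05, 0). Among control macrophages after CCl4, such libraries were mouse 11 for C6 (84.6, 129), Cib3 (1.24, 0), Top2a (684, 454) and Ttk (49.9, 27.3), and mouse 12 for Cyp2c38 (1.04, 0). Mouse 16 for Fabp5 (246, 122) and H2-K2 (26.4, 18.9). Among knockout macrophages after CCl4, such libraries were mouse 17 for Cx3cr1 (172, 88.9), and mouse 13 for Dmbt1 (18.7, 47.7) and Sult3a1 (0.983, 0). Mouse 18 for Gdpd3 (15.2, 1.47) and Myo5a (17.9, 27.2).

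Genotypes differed in their CCl4 effect, by the tested interaction (adjusted p under 0.05, edgeR), for these genes named in the text, with the log2 difference. In hepatocyte libraries, where RNA of macrophages was not told apart, they were Abca8a (1.61), C3ar1 (-4.07), Ccl3 (-4.72), Fabp7 (-6.78), Ifi27l2a (-4.67), Krt23 (3.98), Mmp12 (-5.96), Nid1 (-3.18). In macrophages they were Cd36 (-2.2), Cyp2c54 (7.85), Cyp8b1 (5.72), Emp1 (-3.38), F13a1 (-3.58), Fabp5 (-3.86), Gdf3 (-5.47), Gpnmb (-6.04), Il7r (-2.93), Lgals3 (-2.96), Lpl (-2.98), Lsp1 (-2.45), Mettl7a1 (2.97), Myo5a (-3.04), Stap1 (-3.42), Sult2a8 (7.15), Syngr1 (-5.06). As lists, lipid-associated macrophage markers (median -2.41) and monocyte markers (median -1.80) differed, with estimated-correlation adjusted p = 0.0256 for each. Differences at Nid1, Cd36, Emp1, Il7r, Lsp1, Myo5a and Stap1 are of genes named in the text for another comparison.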

How the results depend on the processing

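Chosen only after the result was seen were the second series alone, thinning, leaving out mitochondrial transcripts, hepatocyte transcript scores as terms, and the series as a term in gene list tests and in the overlap. The cause was not tested where a count moved, except that fewer libraries (second series, 1 library left out, groups of the contrast alone) or fewer reads (thinning) remove power. A sex term was not run, since transcripts of Xist and of Y-linked genes were those of females in every library, and the first series alone gives no genotype comparison. No paired analysis was possible because no mouse was shared between groups within a cell type. Depth limits genes of low abundance, where 3 counts were 0.398 to 5.03 CPM. Of 1641 values of 187 called results of named genes under alternatives set beforehand, 1446 stayed called in the same direction, 194 passed no longer and 1 reversed, Tagln in hepatocytes after CCl4 (0.15 with mouse 15 moved to the knockout group). Of 3194 values with 1 library left out 2769 stayed called and 425 did not, and of 722 under added alternatives 561 and 161. Of 22 named results that were not called, 47 of 197 values under the alternatives set beforehand, 16 of 372 with 1 library left out and 5 of 87 under added alternatives were called.

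Counts that moved by over 1.5 times are given as H for hepatocytes and M for macrophages, with C for CCl4 in controls, K for knockout without CCl4, A for knockout after CCl4, D for CCl4 in knockout mice and I for the interaction. The series as a term gave HK 79, HA 3, HI 54 and MK 34. The second series gave HC 502, HK 50, HA 1, HI 0, MC 867, MA 0 and MI 7 (edgeR). Thinning gave HK 303, HA 8, HI 0, MK 9 and MI 12. Fits of the contrast's own groups gave HK 336, HA 50, MK 257, MA 0 and MD 14. No filter on low counts gave HA 38, HI 113, MK 677, MA 392, MD 431 and MI 697. DESeq2 gave HA 50, HI 46, MK 153, MA 39, MD 200 and MI 152, and limma voom HA 49, HI 6, MK 29, MA 3 and MI 8. RLE factors gave HI 34 and MK 28, fits that were not robust MK 29, and leaving out mitochondrial transcripts HI 37. Leaving out the library with conflicting labels gave HA 4 and HI 2, and moving it to the knockout group HA 0, HI 0, MK 34, MA 0, MD 178 and MI 6. The hepatocyte score as a term gave MK 183 and MD 276, and with the series as well MK 298, MA 1 and MD 311. Beside the counts of 0, unadjusted p under 0.05 held for 1241 (HA), 987 (HI) and 871 (MA) genes with all libraries.

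With 1 library left out the counts ranged over 2020 to 2755 (HC), 288 to 935 (HK), 4 to 130 (HA), 751 to 1398 (HD), 0 to 93 (HI), 903 to 1578 (MC), 1 to 50 (MK), 0 to 10 (MA), 18 to 123 (MD) and 10 to 111 (MI), and the libraries are named in the report. Lists called by camera numbered 19, 17, 8, 18 and 17 in HC, HK, HA, HD and HI, and 14, 13, 10, 9 and 12 in macrophages. With an estimated correlation they were 0, 0, 0, 1 and 0, and 0, 0, 2, 1 and 2, the 1 in HD and MD being mitosis and the 2 in MA and MI the lipid-associated and monocyte lists. Fry gave 9 (HK), 1 (HA), 7 (HI), 8 (MC), 0 (MK), 2 (MA), 2 (MD) and 4 (MI), and the second series 16 in HA. The 9 hepatocyte genes shared by both knockout effects were 517 at unadjusted p, 2 without the library with conflicting labels, 1 with the series as a term and 0 in the second series (edgeR, 96 at unadjusted p), and the 0 shared macrophage genes were 171 at unadjusted p.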

Other observations

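Genes in the next 3 paragraphs were chosen after their values were seen, and no test of an explanation was run on them.

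Knockout mouse 20, without CCl4, had the highest values of division genes among uninjured knockout mice in both cell types. Its hepatocyte library held 40.7 CPM of Mki67 and 71.1 CPM of Top2a, where the other 4 of the group held at most 4.62 and 11.3 CPM. Its macrophage library held 173 CPM of Top2a and the other 3 between 45.1 and 60.5 CPM. The mean over the mitosis list was 4.24 in its hepatocytes and 4.98 in its macrophages, and at most 1.30 and 3.62 in the other mice of those groups.

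Transcripts of pancreatic enzymes were present in libraries of particular mice. In hepatocytes Pnlip stood at 554 CPM in mouse 6, 162 in mouse 15, 54.2 in mouse 16 and 29.1 in mouse 7, all controls, and at 14.1 in knockout mouse 17. In macrophages it stood at 52.3 CPM in mouse 6, 39.0 in mouse 7, 41.9 in mouse 15 and 9.32 in knockout mouse 17. Ctrb1 stood at 70.4 CPM in hepatocytes and 26.4 in macrophages of knockout mouse 17. Control mice 6 and 15 held more, 682 and 236 in hepatocytes and 38.2 and 44.0 in macrophages. Control mice 16 and 7 held less, 58.8 and 42.6 in hepatocytes and 7.28 and 10.4 in macrophages.

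Mup20, a major urinary protein gene whose reads can be shared with its relatives, lay between 146 and 232 CPM in the 4 knockout hepatocyte libraries after CCl4 and between 2.29 and 9.93 CPM in the 3 controls (5.33, SE 1.36, adjusted p = 0.167, edgeR's quasi-likelihood test). The organic anion transporter Slco1a1 lay between 0.722 and 6.68 CPM in 5 knockout and between 10 and 165 CPM in 6 control hepatocyte libraries without CCl4 (-4.27, SE 1.46, adjusted p = 0.0841). Neither passed the threshold.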
